A study of Mus musculus with 6 samples.

How the data were processed

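The series profiled microRNAs (miRNAs), short RNAs that lower the output of target mRNAs, in cultured mouse vascular smooth muscle cells with and without TNF-α. Per the labels, total RNA of each culture was tailed, joined to an oligonucleotide tag and stained with Cy5, so each of the 6 arrays has 1 colour. The scanner, its software and the release of the reporter names are not given in the sources used here.

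For each array the authors deposited 1 median density and 1 standard deviation per reporter, which are intensities on a linear scale per the file headers. The values show that background had not been subtracted, because dim reporters lay near the same density on an array and never near 0. The authors also deposited a table of processed intensities for the same arrays, whose lowest value was 0.01 on every array and whose medians ran from 8.39 to 12.0. Set against the scanner densities of reporters above 150, the commonest difference was 69.11 on each control array and 83.65 on each TNF-α array, within a tolerance of 0.05. That difference held for 82.0% of such reporters on control replicate 1 and for 68.9% on TNF-α replicate 1, and for at most 27.0% on the other arrays. How the processed table was scaled between arrays, and whether the 2 groups were scaled together, stays unknown, so the scanner densities were the main source and the table an alternative. All columns of the table were assigned to samples.

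Scanner densities were corrected with the normexp method and an offset of 50, taken to log2 and quantile normalized between arrays in limma 3.58.1 under R 4.3.3. A reporter was tested when its corrected density, before the offset, reached 32 on at least 3 arrays, which 642 of the 1078 reporters did. The model had the group as its only term, and limma's moderated test was two-sided, with Benjamini-Hochberg adjustment over all tested reporters and a threshold of 0.05. Fold changes are TNF-α over control on this offset scale, which understates changes. Errors are standard errors (SE) from the model unless given as SD.

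Because the normexp fit let many dim reporters through, a background limit was set after the densities were seen. It is the peak of an array's density distribution plus 3 SD of the values below the peak. A reporter is called clear of background when it exceeds this limit on at least 3 arrays, and near background otherwise. Where a reporter exceeded the limit on no array of 1 group, a fold is given only as a bound. The bound sets the mean of the brighter group against the mean, per array, of the higher of the dim value and the lowest value above the limit. No fold is given where this was under 1 or where both groups were below the limit.

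Before the data were examined, the grouping, the test, the filter, 20 lists of miRNAs, the rule for naming miRNAs and most alternatives had been fixed. The rule names the 12 largest rises and the 12 largest falls past the threshold with nonoverlapping groups, up to 4 members of each list by smallest p, and the 5 brightest reporters. List members were matched by exact name, with older miRBase names used where the newer one was absent. Lists with at least 3 tested members, 16 of them, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. The alternatives were 3 other scalings, offsets of 8 and 128, filters at 100 and 500 and on all 6 arrays, no filter, the processed table with 32 added, other variance models, the replicate number as a block and each array left out in turn. The background limit as a filter, and subtraction of the background peak, were added after seeing the data. Normexp with local background and a slide term could not be run because neither background nor slide was given in the files used here.

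The procedure was tested on 20 simulated data sets of 1078 reporters with the levels, backgrounds and spread of these arrays and 100 changed reporters clear of background. Simulated as TNF-α against control, with a median of 481.5 reporters tested, it recovered 80.8% of the changes of 1 on the log2 scale and 46.4% of those of 0.5. False calls made up 9.09% of all calls and 5.71% of calls clear of background. The data had more tested reporters, 642. Simulated sets of arrays differed only in the background and scale of each array, besides the changes put in. The shares of false calls therefore need not hold for the calls in the data, in particular near background. A true change of 1 was estimated at 0.66 in the median, and 1 of 0.5 at 0.30. A list of 8 members shifted by 0.5 was called by camera in 20 of 20 runs and an unshifted list in 1, at an unadjusted p under 0.05.

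Per the labels the cultures were grown separately, so p-values measure the spread between cultures that remains after quantile normalization. That step gives each rank the same value on every array, so an SD on its scale can be 0. Among the miRNAs named by rule it was 0 for miR-130a, miR-21 and miR-709 with TNF-α and for miR-3960 in controls. Their densities had SDs of 103, 2116, 4667 and 2758 in those groups. For such reporters the p-values do not measure the spread of the densities. The descriptions of TNF-α replicates 2 and 3 carry the same replicate number, while their titles differ. Their arrays correlated at 0.993 over tested reporters, inside the range of the other pairs of the same group, and were kept as separate samples. Gene neighbours were read from a RefSeq table of assembly GRCm38.p6, by gene name only. Reporter sequences were not used here, so related miRNAs that a reporter could also bind cannot be separated. Figures were drawn with matplotlib 3.10.9.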

Results

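Vascular smooth muscle cells (VSMCs), the contractile cells of the arterial wall, came from the abdominal aorta of C57BL/6 mice aged 8 weeks and were grown in culture. Untreated cultures (n = 3) were compared with cultures treated with TNF-α (n = 3), an inflammatory cytokine, to ask which miRNAs differ between them. The dose and duration of treatment are not given in the sources used here. Each array read 1078 mouse miRNA reporters under older miRBase names, in which an asterisk marks the less abundant arm of a hairpin. The median density was 74.7 to 82.7 on the control arrays and 85.9 to 97.2 on the TNF-α arrays. The background peak was likewise higher with TNF-α, at 82.0 to 91.4 against 68.4 to 76.8. The number of reporters above the background limit was 284 to 324 on control arrays and 228 to 250 on TNF-α arrays. Over tested reporters, which are not independent replicates, arrays of the same group correlated at 0.992 to 0.996 and arrays of different groups at 0.985 to 0.988. The background peak and the number of reporters above the limit separated all TNF-α arrays from all control arrays. Slides are not given in the files used here. A technical difference between the sets of arrays therefore cannot be told apart from an effect of TNF-α. The number of arrays limits the precision of every value.

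TNF-α cultures differed from controls at 146 of the 642 tested miRNAs, of which 83 were higher and 63 lower. miR-341* and miR-3084 rose more than 2-fold, and miR-3102-5p.2 fell more than 2-fold. These 3 miRNAs were the only ones to change that much past an adjusted p of 0.05 in limma. The median size of the changes was 0.38 on the log2 scale, and the estimates of 20 miRNAs reached 1.5-fold. Among the 20, miR-466k, miR-488*, miR-193b* and miR-1940 have no fold by the background rule, and miR-1188 only a bound below 1.5-fold. Among the 278 tested miRNAs clear of background, 45 rose and 44 fell. Among the 364 near background, 38 rose and 19 fell, but 117 of the 364 reached the minimum of the filter on the 3 TNF-α arrays and no control array, and 3 the reverse. With no filter 44 rose and 40 fell among the 800 near background, and 84 rose and 78 fell in all; with the filter on all 6 arrays 50 rose and 58 fell. All 146 had TNF-α values outside the range of the control values, as did 257 of all tested miRNAs (40.0%). Chance gives 10% for reporters not chosen by their values. The 117 and 3 reporters above, however, passed the filter with groups already separated before normalization, so 10% is no reference for the tested set.

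The balance of rises and falls moved with the scaling of the arrays and with the set of reporters tested. Against the 83 higher and 63 lower with quantile normalization, there were 163 higher and 41 lower with no normalization, 126 and 60 with scaling to the median of detected reporters, and 87 and 73 with cyclic loess. In the authors' processed table, which differs in its background, scaling and offset as well as in the 285 reporters tested, 39 were higher and 81 lower. With quantile normalization and only the 278 reporters clear of background tested, 51 were higher and 55 lower. The median change of all tested miRNAs was 0.01 with quantile normalization, 0.14 without normalization and -0.12 in the processed table. The number of changed miRNAs was 84, 70 and 91 without control replicates 1, 2 and 3, and 88, 79 and 83 without TNF-α replicates 1, 2 and 3. Fewer reporters reached the filter there, 614 to 626 without a control array and 500 without a TNF-α array.

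**Figure D1:**
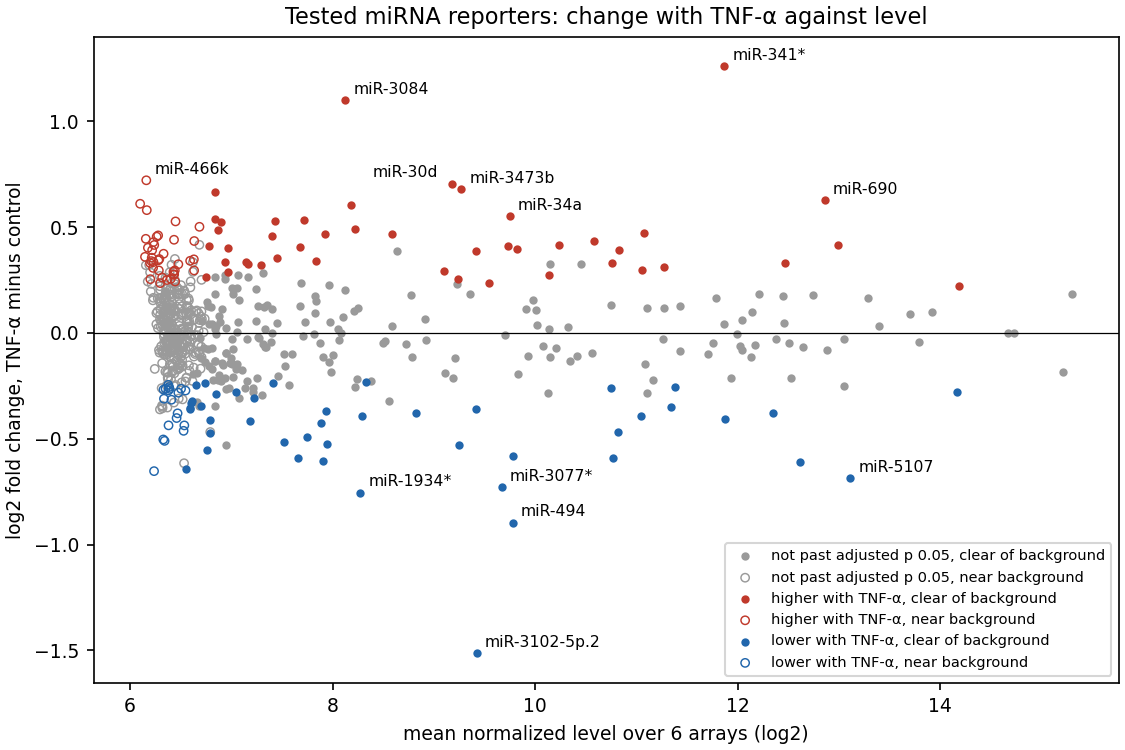
Each point is 1 of the 642 tested reporters, placed by its mean normalized level over the 6 arrays (log2, horizontal) and its log2 fold change, TNF-α minus control (vertical). Red and blue mark the 83 higher and 63 lower miRNAs, grey the others, and open points reporters near background. miR-341* and miR-3084 stand apart above, and miR-3102-5p.2 below.

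The miRNAs that rose most with TNF-α were miR-341*, miR-3084, miR-30d, miR-3473b, miR-690, miR-29b and miR-34a among those clear of background on all arrays. miR-341*, from the imprinted Dlk1-Dio3 locus, rose 2.40-fold (log2 1.26 ± 0.09, SE, n = 3 per group, adjusted p = 0.000162), from a density of 2566 ± 577 (SD, n = 3) to 6086 ± 524. miR-3084 rose 2.15-fold (log2 1.10 ± 0.11, adjusted p = 0.000979), from 190.1 ± 10.7 to 397 ± 45.9. miR-30d rose 1.63-fold (0.71 ± 0.07, adjusted p = 0.000979) and miR-690 1.55-fold (0.63 ± 0.07, adjusted p = 0.00114). miR-29b, of a family that represses collagen mRNAs, rose 1.52-fold (0.60 ± 0.08). miR-34a, a transcriptional target of p53, rose 1.47-fold (0.55 ± 0.07), and miR-3473b 1.60-fold (0.68 ± 0.18). miR-1188 and miR-3473 exceeded background on the 3 TNF-α arrays and on no control array, and were at least 1.41-fold and at least 1.35-fold higher. miR-466k, miR-488* and miR-669a-5p, which complete the 12, passed the test but exceeded background on no array, so no fold is given.

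The call of miR-34a was lost without normalization (0.26), with median scaling (0.20) and in the processed table (0.23), and miR-30d was 0.43 with median scaling and 0.46 in that table. The call of miR-3473b was lost with an offset of 8 (0.73), with a trended robust variance (0.68), and without control replicates 1 (0.72), 2 (0.68) or 3 (0.62) or TNF-α replicates 1 (0.56) or 3 (0.58).

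The miRNAs that fell most were miR-3102-5p.2, miR-494, miR-1934*, miR-3077*, miR-5107, miR-467b*, miR-669h-3p, miR-1224, miR-714 and miR-5130, each clear of background on all arrays. miR-3102-5p.2 was 2.86-fold lower (log2 -1.51 ± 0.11, adjusted p = 0.000162), at a density of 386 ± 41.6 (SD, n = 3) against 1290.1 ± 227 in controls. miR-494, a member of the Dlk1-Dio3 locus, was 1.86-fold lower (-0.90 ± 0.10, adjusted p = 0.00114), at 616 ± 108 against 1290.5 ± 146. miR-1934* (-0.75 ± 0.18), miR-3077* (-0.73 ± 0.11) and miR-5107 (-0.69 ± 0.15) were 1.69-fold, 1.66-fold and 1.61-fold lower. The remaining 5 lay between miR-5130 (-0.58 ± 0.10) and miR-467b* (-0.61 ± 0.07, 1.53-fold lower). miR-1940 passed the test (-0.64) but exceeded background on control arrays only, and miR-193b* (-0.65) on no array, so neither has a fold.

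The call of miR-1934* was lost without control replicates 1 (-0.71), 2 (-0.77) or 3 (-0.77) or TNF-α replicate 3 (-0.81), that of miR-5107 without control replicate 1 (-0.56), and that of miR-1940 without any 1 of the control replicates (-0.70, -0.59 and -0.62) or TNF-α replicates 1 (-0.61) or 3 (-0.52). miR-3077* was -1.10 and miR-5130 -0.90 in the processed table.

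**Figure D2:**
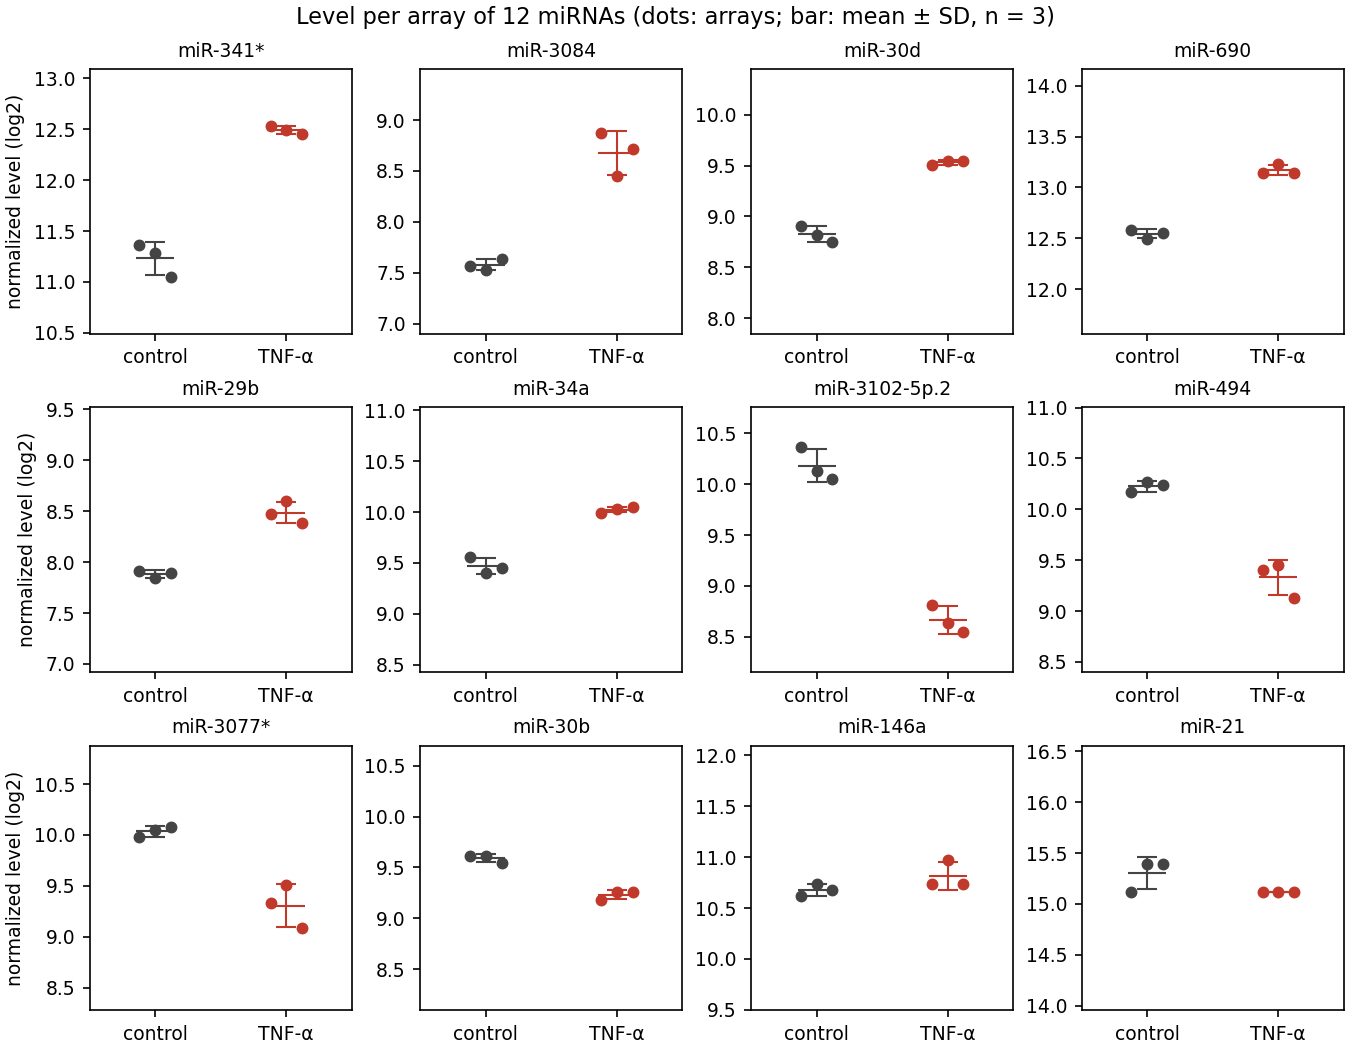
Normalized level (log2, vertical) of 12 miRNAs on each array, with control cultures in grey and TNF-α cultures in red; dots are arrays and bars the mean ± SD (n = 3), and every panel spans the same log2 range. The groups do not overlap for the 10 changed miRNAs, and miR-146a and miR-21 did not pass the test.

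miRNAs known to be induced by TNF-α and NF-kB in other cells did not rise among those tested, which were 10 of the 13 list members on the arrays. miR-147 was among those not tested. Of 10 tested members of that list, 6 of them clear of background, 0 rose and 1 fell by limma, both over all miRNAs tested and adjusted over the list alone; at an unadjusted p under 0.05, 0 were higher and 2 lower. miR-146a, a feedback inhibitor of NF-kB signalling, changed by 0.13 ± 0.09 (adjusted p = 0.307), with a 95% interval of -0.06 to 0.33. The offset scale understates changes, but for miR-146a the offset mattered little, with 0.14 at the smaller offset and 0.13 at the larger. The density of miR-146a was 1711 ± 144 (SD, n = 3) in controls and 1705 ± 183 with TNF-α. Its change was -0.01 without normalization and -0.07 in the processed table, and at most 0.19 under any alternative. miR-146b changed by -0.22 ± 0.08 (adjusted p = 0.0755) and miR-21 by -0.18 ± 0.09 (adjusted p = 0.171). miR-146b passed as lower with median scaling (-0.34), with a filter at 100 (-0.22) and in the processed table (-0.46). miR-21 passed as lower without control replicate 1 (-0.29), but it was 0.08 without normalization, 0.02 with median scaling and 0.12 in the processed table. Its density was 36394 ± 2489 (SD, n = 3) in controls and 38342 ± 2116 with TNF-α. With quantile normalization it only exchanged the top ranks with miR-709, so its change there does not measure its density. miR-146a was -0.06 with median scaling. The member that fell was miR-155 (-0.27 ± 0.07, adjusted p = 0.0279), which exceeded background on no array and lost its call without normalization (-0.09), with median scaling (-0.14), and without control replicates 1 (-0.27) or 2 (-0.24) or TNF-α replicates 1 (-0.25) or 3 (-0.26).

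Among miRNAs of the contractile VSMC state, 0 of 6 tested members rose and 1 fell, over all tested and adjusted over the list alone. This was miR-145* (-0.51 ± 0.08, adjusted p = 0.00496), the minor arm of the miR-145 hairpin, above background on 1 control array and no TNF-α array, with no bound above 1 and a value of -0.33 without normalization. The abundant arm, miR-145, was at 5151 ± 620 in controls and 6173 ± 646 (SD, n = 3) with TNF-α and did not pass (0.17 ± 0.09, adjusted p = 0.217). miR-10a (0.05) and miR-133b (-0.06) did not pass; miR-133b was 0.12 without normalization and miR-10a was -0.04 in the processed table. Among miRNAs linked to VSMC proliferation, 1 of 8 rose and 0 fell, again by both adjustments. miR-130a rose by 0.28 ± 0.07 (adjusted p = 0.0237), but it was -0.01 with median scaling and its call was lost under 11 of 21 alternatives, among them each array left out except control replicate 2 (0.26 to 0.29 in those 5). miR-26a, at 0.18 ± 0.12, did not pass.

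In several abundant families some members passed the test and others did not, and in the miR-30 family members passed in both directions. In the miR-30 family, 2 of 9 tested members rose, miR-30d and miR-30a, and 1 fell, miR-30b (-0.36 ± 0.07, adjusted p = 0.00837), by both adjustments. miR-30b was -0.59 with median scaling and -0.62 in the processed table. miR-30a (0.24 ± 0.06) was -0.01 with median scaling and lost its call under 11 of 21 alternatives, with values of 0.20 to 0.25 where control replicates 1, 2 or 3 or TNF-α replicates 1 or 2 were left out; miR-30e was -0.16 and did not pass. In the miR-29 family 2 of 7 rose and 0 fell, also adjusted over the list alone. These were miR-29b and miR-29c (0.43 ± 0.10, adjusted p = 0.0175), while miR-29a* (0.12) and miR-29b-2* (-0.07, positive without normalization and with median scaling) did not pass. The call of miR-29c was lost without normalization (0.34), with median scaling (0.28) and without control replicate 1 (0.39). In the miR-199 and miR-214 group 2 of 5 rose by both adjustments, miR-199b* (0.47 ± 0.07) and miR-199a-5p (0.42 ± 0.08). The other arm miR-199a-3p (-0.25 ± 0.10, adjusted p = 0.0986) and miR-214* (-0.16) did not pass. With median scaling miR-199b* (0.25) and miR-199a-5p (0.21) lost their calls, the latter also without normalization (0.27) and in the processed table (0.24), where miR-199b* was 0.31 and 0.27.

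In the miR-15 and miR-16 family, 1 of 7 tested members rose, miR-15b (0.41 ± 0.07), and 1 fell, miR-322 (-0.25 ± 0.07), which exceeded background on control arrays only and has no bound above 1. miR-503 (0.19) and miR-497 (0.19) did not pass. In the miR-17 cluster and its paralogues, which promote cell cycle progression, 1 of 10 rose, miR-25 (0.39 ± 0.08, adjusted p = 0.0115). miR-93 (0.39 ± 0.12, adjusted p = 0.0567), miR-92a (-0.29) and miR-19b (-0.09) did not pass. Of the miR-34 family 1 of 4 rose, miR-34a, beside miR-34c* (0.24), miR-34b-3p (0.13) and miR-34c (0.10), which did not pass. Of the miR-23, miR-27 and miR-24 clusters 1 of 9 rose, miR-24-2* (0.41 ± 0.08), and miR-27a (0.18), miR-23b (0.10) and miR-23a (0.09) did not pass. These counts were the same adjusted over each list alone. miR-15b (0.17, 0.12 and 0.11) and miR-25 (0.23, 0.17 and 0.25) lost their calls without normalization, with median scaling and in the processed table, and miR-322 lost its call under 9 of 18 alternatives, including each array left out (-0.27 to -0.21).

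Of the miR-99, miR-100, miR-125 and miR-10 group 1 of 7 fell, miR-99b (-0.26 ± 0.08, adjusted p = 0.0432), and 0 did so adjusted over the list alone. miR-100 (0.18), miR-99a (0.07) and miR-10b (0.12) did not pass, and the first 2 changed sign with median scaling. Of the let-7 family only miR-98 was measured, and it fell (-0.37 ± 0.11, adjusted p = 0.0459); the other members were not analysed here. Among 11 tested miRNAs of the Dlk1-Dio3 locus 3 rose and 2 fell, by both adjustments. Of these 5, only miR-494 was clear of background. The list was fixed without miR-341*, which lies in the same locus, and its neighbour miR-1188, which both rose. miR-377 was at least 1.20-fold higher, from no control array and 2 TNF-α arrays above background, whereas miR-127, miR-382 and miR-323-3p passed the test without exceeding background in both groups. miR-99b was -0.43 with median scaling and -0.40 in the processed table, and miR-377 was 0.84 in that table. The calls of miR-99b and miR-98 were each lost under 9 alternatives, among them all 6 arrays in turn for miR-99b (-0.29 to -0.23) and all except TNF-α replicate 3 for miR-98 (-0.41 to -0.27). The call of miR-127 was lost without control replicates 1 (0.24) or 2 (0.28) and that of miR-323-3p without normalization (-0.08), with median scaling (-0.13) and without TNF-α replicates 2 (-0.26) or 3 (-0.26).

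Markers of other cell types were mostly dim. The 4 liver and gut markers lay lower together, with a median of -0.33, and camera called the list lower (adjusted p = 0.0391). With an estimated correlation the list was not called (adjusted p = 0.915 with an estimated correlation, 0.0695 before adjustment). Its camera call was also lost without normalization (-0.20), with median scaling (-0.26), with the larger offset (-0.19), with the replicate block, and without control replicates 2 (-0.31) or 3 (-0.31) or TNF-α replicates 1 (-0.38), 2 (-0.28) or 3 (-0.39). Over all miRNAs tested 3 of them fell and adjusted over the list alone 4 did. miR-194 was at least 1.11-fold lower (-0.56 ± 0.10, adjusted p = 0.00819; -0.92 in the processed table), above background on control arrays only, and miR-192 changed by -0.26 ± 0.09 (adjusted p = 0.0599). miR-215 (-0.40) exceeded background on no TNF-α array and miR-122 (-0.26) on no array. The call of miR-215 was lost under 10 of 15 alternatives, including control replicates 1 (-0.46), 2 (-0.38) or 3 (-0.36) and TNF-α replicates 2 (-0.29) or 3 (-0.42) left out, and that of miR-122 under 5, including without control replicates 2 (-0.24) or 3 (-0.26) or TNF-α replicate 2 (-0.27). The remaining 15 lists that camera tested had adjusted p of 0.448 to 0.934. The mean and the median change differed in sign for the miR-29, miR-30, miR-15 and miR-16 lists and for the miR-199 and miR-214 group.

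Among striated muscle markers 1 of 3 fell, miR-206 (-0.49 ± 0.07, adjusted p = 0.00339), at 189 ± 17.7 against 257 ± 19.9 in controls (SD, n = 3), while miR-133a (-0.04, turning sign without normalization) did not pass. Among blood cell markers 1 of 2 rose, miR-181a (0.39 ± 0.08, adjusted p = 0.0115), which many cell types express, and miR-150 (-0.16, 0.01 without normalization) did not pass. The call of miR-181a was lost without normalization (0.24), with median scaling (0.19), in the processed table (0.20) and without control replicate 2 (0.38). None of the tested endothelial (1), epithelial (1) or neural (3) markers passed in limma, and 1 did at an unadjusted p under 0.05; these were miR-126-3p (-0.17), miR-203 (0.07), miR-124 (-0.25), miR-129-5p (-0.02) and miR-128 (0.02), the last 2 changing sign with median scaling. The single-marker counts were the same adjusted over each list alone.

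Entries suspected of being fragments of other RNAs, a sign of RNA quality, moved both ways, with 2 of 8 higher and 2 lower by both adjustments. miR-2137 (0.33 ± 0.06) and miR-5115 (0.33 ± 0.10) rose, and miR-2861 (-0.41 ± 0.07) and miR-3960 (-0.28 ± 0.07) fell. The call of miR-5115 was lost under 10 of 21 alternatives, including each array left out except TNF-α replicate 3 (0.25 to 0.36), and that of miR-3960 under 6, including control replicates 1 (-0.26), 2 (-0.26) or 3 (-0.27) and TNF-α replicate 3 (-0.23) left out; miR-3960 was -0.45 with median scaling and -0.49 with cyclic loess. The 5 brightest reporters were miR-709, miR-21, miR-125b-5p, miR-5126 and miR-3960. Quantile normalization gives each rank the same value on every array. miR-5126 and miR-125b-5p exchanged ranks alike in both groups and so were at 0.00, against 0.37 and 0.14 without normalization, and miR-709 was at 0.18 against 0.50. miR-21 and miR-709 exchanged the top ranks, so the -0.18 of miR-21 mirrors the 0.18 of miR-709.

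**Figure D3:**
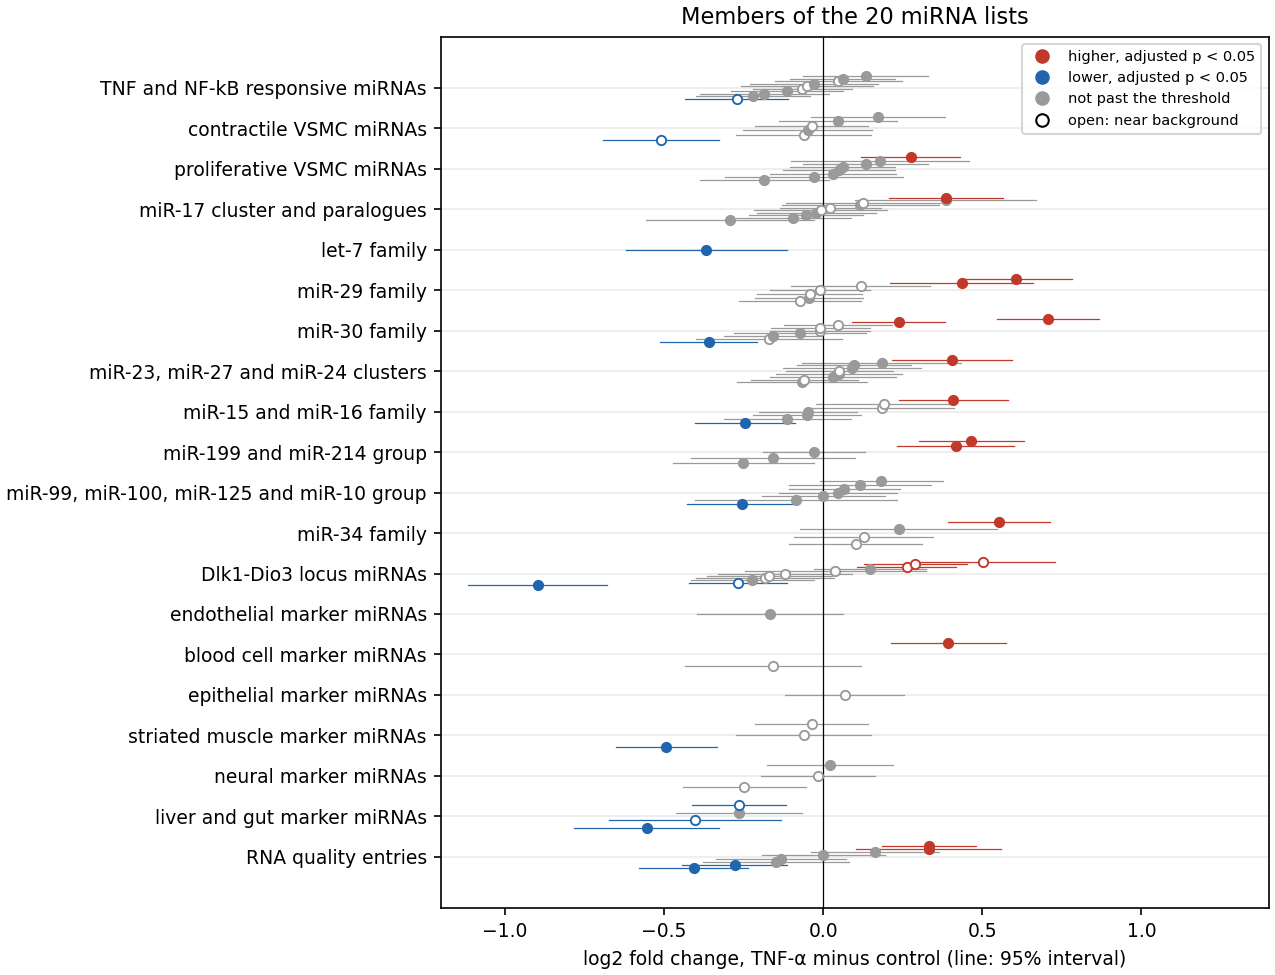
Log2 fold change, TNF-α minus control (horizontal, with 95% intervals), of every tested member of the 20 lists (vertical). Red and blue mark members higher or lower past an adjusted p of 0.05, grey the others, and open points those near background; in most lists members lie on both sides of 0, and the 4 liver and gut markers all lie below it.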

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

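The comparisons used the median density alone. The standard deviation given with it, divided by the density, was higher on all 3 TNF-α arrays than on all 3 control arrays for 41 of the 278 reporters clear of background, and lower for 22, where chance gives 5% each way. Its median over these reporters was 9.82%, 9.98% and 10.2% on the control arrays and 9.65%, 10.03% and 9.89% on the TNF-α arrays. What repeats this standard deviation covers is not given in the sources used here.

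Of the 436 untested reporters, 4 exceeded the background limit on a TNF-α array and on no control array, and 3 did the reverse. miR-147, which inflammatory signals induce in macrophages, is an untested member of the list of miRNAs induced by TNF-α and NF-kB. It reached 187 on TNF-α replicate 1, against 90.3 and 72.6 on the other TNF-α arrays and 71.9 to 85.6 on the control arrays. miR-432 reached 219.8 on TNF-α replicate 1, against 60.8 and 54.8 on the other TNF-α arrays and 59.1 to 66.0 on controls. miR-3083* reached 132 on TNF-α replicate 1, and its other arrays lay between 69.0 and 87.2. miR-3076-5p reached 142 on TNF-α replicate 3 and 127 on replicate 1, with 72.8 on replicate 2 and 72.3 to 86.2 on controls. No more than 2 of 3 TNF-α arrays showed any of these. The 3 on the control side each exceeded the limit on 1 control array. miR-26b* reached 127 and miR-377* 137 on control replicate 3, and miR-743b-5p reached 132 on control replicate 2.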

How the results depend on the processing

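The background limit as a filter and the subtraction of the background peak were chosen after seeing the data. The 146 changed miRNAs became 77 with a filter at 100 and 45 at 500, where fewer reporters were tested (189 and 102). They became 70 to 91 with an array left out, where fewer samples were fitted. Fewer reporters were also tested there, since the filter still asked for 3 arrays. Tested were 614 to 626 without a control array and 500 without a TNF-α array. The 83 higher became 163 without normalization, 126 with median scaling, 39 in the processed table, 38 and 23 with filters at 100 and 500, 50 with the filter on all 6 arrays, 51 with the background limit as a filter, 51 after subtracting the background peak, and 37 to 56 with an array left out. The 63 lower became 41 without normalization, 39 and 22 with filters at 100 and 500, and 26 to 47 with an array left out. For the scalings the cause was not tested. Cyclic loess kept 137 of the 146 calls, and 98 passed in the same direction under all 3 other scalings. Every array left out in turn kept 48, 24 higher and 24 lower, where a call no longer tested counts as lost. The liver and gut list, at -0.33, lost its camera call without normalization (-0.20), with median scaling (-0.26), with the larger offset (-0.19), with the replicate block (-0.33) and with an estimated correlation (-0.33), and its values were -0.39 to -0.28 with an array left out; the cause was not tested. miR-130a turned to -0.0127 and miR-30a to -0.0102 with median scaling, and the cause was not tested.

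Of the 50 changed miRNAs named by rule, 27 passed under every alternative that tested them. Among the 27, miR-466k, miR-488*, miR-669a-5p, miR-193b* and miR-145*, all near background, were tested under only 12 of 21 alternatives. Values near background moved with the offset, as for miR-466k, at 1.91 with an offset of 8 and 0.35 with the larger, and with the scaling, as for miR-29a*, at 0.31 without normalization against 0.12. With the replicate number as a block, 103 miRNAs changed, 55 higher and 48 lower. Deviations of same-numbered samples correlated at 0.04, 0.02 and 0.15, and 3 of the 6 samples correlated best with their own number. Only the numbers in the titles were tried, and 3 pairs are too few to decide whether the numbers pair the cultures. Normexp with local background, a slide block and the merging of identical arrays were not run.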

Other observations

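Outside the lists, individual members of several families passed the test, and no family was tested as a group; the miRNAs named in this and the next paragraph were picked after their values were seen. The miR-466 family, whose many copies lie with miR-467 and miR-669 in an intron of Sfmbt2, had 8 of 20 tested reporters higher and 0 lower, 5 of the 8 clear of background. miR-466j (0.53 ± 0.11) and miR-466f (0.35 ± 0.07) rose, the call of miR-466j being lost without control replicate 2 (0.46). In the miR-467 family 1 of 9 rose, near background, and 3 fell, all bright, namely miR-467b*, miR-467d* (-0.38 ± 0.07) and miR-467a* (-0.39 ± 0.10). The call of miR-467a* was lost with an offset of 8 (-0.40), with the replicate number as a block (-0.39) and without control replicates 2 (-0.32) or 3 (-0.38) or TNF-α replicates 1 (-0.41) or 2 (-0.34), and its value was -0.61 with median scaling. The miR-669 family had 2 of 22 higher and 1 lower. With miR-297 added, the 54 reporters of these families had 11 higher and 4 lower and a median of 0.04, or -0.02 in the processed table. The family medians of miR-466 (0.25) and miR-467 (-0.11) kept their signs under all 3 other scalings and in the processed table, where they were 0.30 and -0.37, and that of miR-669 (-0.05) turned positive without normalization (0.11) and with median scaling (0.06). miR-324-5p (0.49 ± 0.07) and miR-181c (0.53 ± 0.08) also rose under all 20 alternatives that tested them.

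Neighbouring miRNA genes moved together at some places and apart at others. miR-341* and miR-1188, whose genes are neighbours, both rose. Of the neighbours miR-30d and miR-30b, the former rose and the latter fell under all 21 alternatives. miR-351 rose (0.32 ± 0.09) beside miR-322* (-0.47 ± 0.10, and -0.76 in the processed table), which was above background on control arrays only; the call of miR-351 was lost under 7 of 20 alternatives, among them control replicates 2 (0.31) or 3 (0.26) and TNF-α replicates 2 (0.31) or 3 (0.27) left out. Of 25 hairpins with both arms clear of background, 3 had both arms changed, 2 of them in the same direction, 10 had 1 arm changed and 12 neither. Among the 10, miR-341* rose while miR-341 was at 0.06 ± 0.20, and miR-3102-5p.2 fell while miR-3102 was at 0.09 ± 0.07.

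The tests below of exchanged arrays, of the range of the arrays, of a single RNA population and of the filter, with the trend repeated without it, were chosen only after the result was seen. In the split of the 6 arrays by group 146 miRNAs changed, and the highest count in the other 9 splits was 0; 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05.

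A first pattern is that tested miRNAs known as targets of TNF-α signalling did not rise. The lowest correlation within a group exceeded the highest between groups by 0.00442. This argues against exchanged labels of 1 or 2 arrays of each group once the arrays had been read. With a technical difference between the sets of arrays, samples exchanged before that step could still correlate by set. The correlations therefore cannot decide on such an exchange. For the 5 members other than miR-21, some miRNA within 4-fold of the level of each rose by 1.10 or more. It was miR-341* or miR-3084 each time, and both rises were known before this test was chosen. A rise of that size could thus be read at these levels, but the test cannot decide whether smaller changes were compressed. The scaling is argued against by the 0 list members clear of background that rose under any other scaling or in the processed table. An exchange of all arrays of both groups leaves the correlations unchanged and cannot be told apart from the labelled order, since up to 2 such members passed as lower under an alternative (miR-146b and miR-132 with median scaling, the latter named after its values were seen). At the level of miR-21 the largest rise was 0.22 with 2 miRNAs changed, too few to decide on its range, and its normalized values were bound to the top ranks. The length and dose of treatment were not tested.

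A second pattern is that tested reporters of the miR-297, miR-466, miR-467 and miR-669 families near background lay higher (mean 0.16, SD 0.25, n = 19) than those clear of it (0.01, SD 0.27, n = 35). The background limit was 93.9 to 103.8 on control arrays but 118.0 to 131.6 on TNF-α arrays. A reporter near it that rose could stay near background, as miR-377 did, while a fallen reporter such as miR-194 counted as clear. The difference is thus partly built into the split. The filter admits dim reporters mainly through the TNF-α arrays, but 0.978 of the difference was left with no filter (dim mean 0.16, SD 0.20, n = 37). This argues against the filter as the cause. The split by the background limit stayed in place, so selection by that split cannot be told apart from a change in the RNAs. Other reporters matched on level showed 0.277 of the difference among tested reporters, between the bounds set in advance, so that there a trend with intensity cannot be told apart from a change in the RNAs. With no filter they showed -0.0787 of it, which argues against such a trend over all reporters. Matched reporters were not split by the background limit, so they cannot decide on selection by it. The changes of all these reporters had an SD 3.01 times their median standard error, more than spread within groups alone would give for a single RNA population. Technical differences of single reporters between the sets of arrays do not enter that error. The ratio therefore cannot decide whether these reporters read a single RNA population.

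A last hypothesis was that neighbouring miRNA genes change together. Of 642 tested reporters 549 matched a single gene, which gave 409 genes and 251 pairs within 10000 bases. Their changes were not more alike than shuffled ones (one-sided permutation p = 0.336 with 10000 shuffles, and 0.227 for the 209 pairs with different numbers), so these data give no support for it.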
